A study of Escherichia coli str. K-12 substr. MG1655 with 24 samples.

How the data were processed

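The measurements were RNA sequencing read counts per gene feature in 24 libraries of Escherichia coli K-12 MG1655, from 3 strains, 2 growth conditions and 2 fractions, total RNA and RNA precipitated with an antibody against Hfq. Per the labels, cultures grew at 37 °C in LB with 5 mM sodium nitrate, were split at an OD600 of 0.3 into aerobic and anaerobic parts and were collected at 0.9 to 1.0, and lysates of 20 OD600 units gave both fractions. Libraries were made from 400 ng of RNA with 7 PCR cycles and read from both ends.

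The authors deposited a gene table for each growth condition, with 4671 features each, and the growth condition of a column is known only from the heading of its table. Per the file headers 12 columns of each table hold raw counts, but their values are expected counts: the authors deposited values of at least 1 in every cell, and 73.2% to 79.7% of them per library are whole numbers and the rest are mostly multiples of 0.5, as when reads on overlapping features are divided. The other columns hold RPKM per the file headers, counts scaled by feature length and library size, and the divisor behind them exceeds the sum of the counts, which is 87.3% to 89.7% of it in Hfq-IP libraries and 39.7% to 41.7% in total RNA. The submitters' processing notes name cutadapt, FastQC 0.11.9 and DESeq2; the aligner and the counting program are not given in the sources used here. The annotation is on NC_000913.3, and 4496 features (96.3%) matched a RefSeq gene name, of which 97.0% had the same start and end. RPKM was used only to learn the divisor. The design had assumed raw counts; because the unit is expected counts, the values were rounded to whole numbers for the count models. Another deposited table holds tRNAs alone in 24 columns whose names fit both an aerobic and an anaerobic sample, so it could not be assigned and was left out, as were 2 rows without a name. Identical or near-identical tRNA and rRNA copies share reads in ways these tables do not show, so values of single copies depend on how the authors divided them.

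The comparisons, tests, gene lists and alternatives were fixed before the data were examined. Counts were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM, quasi-likelihood F test, Benjamini-Hochberg adjusted p under 0.05), with 1 mean per group of 2 libraries. Comparisons within a fraction used its 12 libraries, and comparisons across fractions used all 24. The filter left 4497 features in Hfq-IP RNA, 4184 in total RNA and 4507 over both, removing 174, 487 and 164. The biological coefficient of variation was 0.175, 0.170 and 0.173 in that order, and TMM factors ranged from 0.903 to 1.13, from 0.853 to 1.26 and from 0.430 to 2.32. An adjusted p given beside a fold change comes from edgeR, and errors are standard errors of its log2 fold changes. CPM are counts scaled to library size with the TMM factors of the fraction.

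The 19 gene lists were Hfq-dependent sRNAs, other stable small RNAs, type I antitoxin RNAs, known sRNA target mRNAs, nitrate respiration, fumarate and DMSO respiration, fermentation, the TCA cycle with aerobic respiration, NADH dehydrogenase I, oxidative stress, the Fur iron regulon, the RpoS regulon, flagella and chemotaxis, sigma E envelope stress, heat shock, RNA binding and decay, ribosomal proteins, rRNA and tRNA. Some genes, such as gltA and rybB, stand in more than 1 list. Each list was tested in limma 3.58.1 with camera at a preset correlation of 0.01, which compares the list with all other genes, again with a correlation estimated from the data, and with fry, whose p asks whether the list's genes move on balance in 1 direction without comparing them with other genes. Their p-values were adjusted over the 19 lists of a comparison. A count adjusted over the list alone comes from the same edgeR p-values adjusted among the list's members.

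Named genes were yhbS and hfq, and in each direction the 8 passing genes with the largest log2 fold change (3 for the secondary comparisons) among those with an average log2 CPM of at least 3 and libraries that did not overlap between the groups, plus up to 4 members per list with the smallest p. RNA class shares were compared between 4 WT and 8 mutant libraries by exact permutation within growth condition, adjusted over the classes, and again among same-numbered libraries, a test added after the data were seen. The fold changes of both mutants were compared with 100 simulated data sets without any effect drawn from the fitted model, with all libraries independent.

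On simulated data with known changes, the aerobic Hfq-IP comparison of the deletion label with WT recovered 62% of 2-fold and 99% of 4-fold changes, the total RNA comparison 76% and 99%, Hfq-IP against total RNA 63% and 98%, and the difference of enrichment 34% and 86%, with 3.31% to 6.40% false among all calls. For Hfq-IP against total RNA the simulated fractions had the same mean for every gene but the changed ones. The measured fractions differed widely in composition, so its shares do not cover errors from scaling between them. Per the labels, Hfq-IP and total RNA of a replicate came from 1 lysate and both growth conditions from 1 culture, so those comparisons are paired. The residuals of such pairs were checked, and correlated at 0.19 to 0.32 between Hfq-IP and total RNA (6 pairs of groups) and at 0.037 to 0.065 in Hfq-IP RNA and 0.018 to 0.078 in total RNA between both growth conditions of a strain (3 pairs of groups in each fraction).

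The alternatives were DESeq2 1.42.0, its size factors in edgeR, library size without TMM, no count filter, an added 2-fold minimum, a replicate block, leaving out each library, all 24 libraries in place of 12 or the reverse, tRNA and rRNA features left out, and for the class shares other denominators. A replicate block within each growth condition was added after the data were seen. The fits that left out a library had no replicate block. Tables were prepared with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3.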

Results

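Total RNA and RNA co-immunoprecipitated with an antibody against Hfq (Hfq-IP RNA) were sequenced from 3 strains of Escherichia coli K-12 MG1655. Hfq is the RNA chaperone that binds small regulatory RNAs (sRNAs) and their target mRNAs, and the strains were WT, a strain labelled as a deletion of hqbA (yhbS in the annotation, an acetyltransferase gene), and a strain whose HqbA protein carried the substitutions D98A and E102A (the point mutant). Each strain was grown aerobically or anaerobically in LB with 5 mM sodium nitrate. The 3 strains, 2 growth conditions and 2 RNA fractions gave 12 groups of 2 libraries each, 24 libraries in all. The total count per library in the gene tables ranged from 10089325 to 31289220 for Hfq-IP RNA and from 13236274 to 28026296 for total RNA. There was no mock precipitation, so Hfq-IP RNA could be compared only with total RNA and between strains. Nothing beyond the labels shows that the 2 libraries of a group came from separate cultures, so the p-values measure the spread between these libraries.

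The altered gene was measured first in every library. Gene yhbS (b3156) lies on the minus strand of NC_000913.3 at 3300255 to 3300758. In aerobic total RNA it was at 69.3 and 96.9 CPM (counts scaled to library size, with TMM factors) in the WT libraries, 54.8 and 82.8 in the point mutant and 30.3 and 27.5 in the libraries labelled as the deletion. In anaerobic total RNA the corresponding values were 66.6 and 60.1 for WT, 60.0 and 61.2 for the point mutant, and 24.5 and 24.8 for the deletion label. The yhbS counts of total RNA therefore fell in the deletion-labelled libraries, by 1.52 ± 0.21 on the log2 scale aerobically (SE, n = 2 per group, adjusted p = 0.0072) and by 1.36 ± 0.21 anaerobically (adjusted p = 0.015), but did not reach 0. Leaving out 1 library brought the aerobic adjusted p to at most 0.067 (without a deletion-labelled replicate), and the anaerobic one lay between 0.096 and 0.25 without any of the 4 libraries. In Hfq-IP RNA the same label had more yhbS counts, not fewer. They stood at 350 and 347 CPM against 77 and 113 in aerobic WT, a rise of 1.87 ± 0.23 log2 (adjusted p = 0.0027), and at 247 and 200 against 95.7 and 73.6 in anaerobic WT (1.40 ± 0.23, adjusted p = 0.019, and 0.071 to 0.17 when any 1 library was left out). Because these counts go against the label, the libraries are called deletion-labelled here.

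Both neighbours of yhbS on the minus strand also rose in the deletion-labelled Hfq-IP libraries. Gene yhbT (3300752 to 3301276, overlapping yhbS by a few bases) rose by 2.44 ± 0.17 log2 aerobically (adjusted p = 3.1e-05) and by 1.82 ± 0.17 anaerobically (adjusted p = 0.00053), while its total RNA differed by -0.11 ± 0.21 and 0.20 ± 0.21 and did not pass the test. Gene yhbP (3299472 to 3299915) rose in Hfq-IP RNA by 3.64 ± 0.18 and 3.24 ± 0.17 log2, from 10.9 and 13.3 to 150 and 153 CPM in the aerobic libraries. It also rose in total RNA, by 3.01 ± 0.26 aerobically (adjusted p = 0.0004) and 2.22 anaerobically (adjusted p = 0.0015, and up to 0.066 with 1 library left out). In total RNA yhbP was below the average abundance that the rule for named genes asked for, and it is named here because it lies at the altered locus. Gene yhbQ, which overlaps the end of yhbS on the plus strand, did not pass the test in Hfq-IP RNA (-0.12, adjusted p = 0.86, and -0.43, adjusted p = 0.47).

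**Figure D1:**
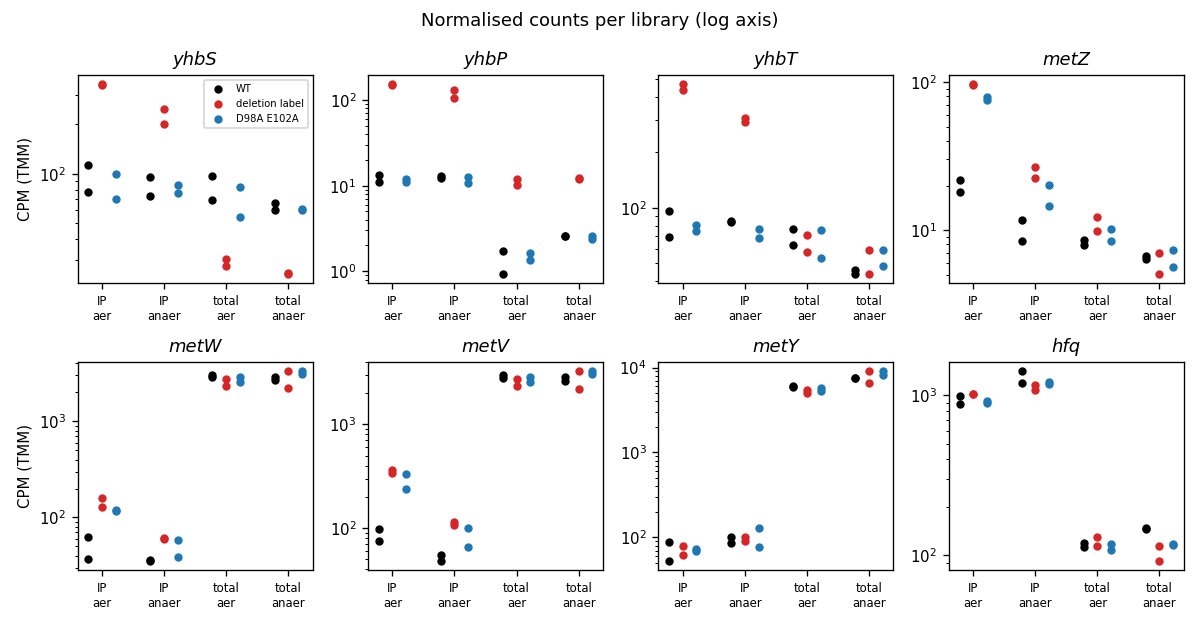
Normalised counts (CPM with TMM factors, log axis) of yhbS, yhbP, yhbT, the initiator tRNA genes metZ, metW, metV and metY, and hfq, with 1 point per library, 2 libraries per group, for WT, the deletion label and the D98A E102A point mutant in aerobic and anaerobic Hfq-IP and total RNA. The deletion-labelled libraries have fewer yhbS counts in total RNA (24.5 to 30.3 CPM) and more in Hfq-IP RNA (200 to 350 CPM) than WT, and metZ is higher in aerobic Hfq-IP RNA of both mutants.

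The RNA classes of the fractions differed widely. The Hfq-dependent sRNAs, 32 features, held 14.5% to 30.4% of the counts of an Hfq-IP library and 0.778% to 1.64% of those of a total RNA library, while tRNAs held 0.433% to 0.833% and 64.8% to 76.8%. The rRNAs held only 0.0415% to 0.0821% and 0.202% to 0.389%. So small a counted part need not stand for the rRNA of the cells in either fraction. In Hfq-IP RNA the sRNA share averaged 20.9% in the 4 WT libraries and 22.9% in the 8 mutant libraries, a difference of 2.00 points with an exact permutation p of 0.267 (two-sided, over all arrangements within growth condition) and an adjusted p of 0.56. The share was above the WT mean of its growth condition in 6 of 8 mutant libraries. The difference was -0.597 points aerobically and 4.60 points anaerobically, where the sRNA share averaged 24.3% in WT, 28.7% under the deletion label and 29.1% in the point mutant. The mRNA share differed by -2.06 points (exact permutation p = 0.258, adjusted p = 0.56, lower in 6 of 8), and no class of either fraction passed, the smallest adjusted exact p in total RNA being 0.853. That permutation ignores the replicate number, although replicate 2 had the higher sRNA share in all 6 Hfq-IP groups. Permuted only among same-numbered libraries, which was added after the data were seen, the sRNA and mRNA shares of Hfq-IP RNA each had an exact permutation p of 0.0988 (adjusted p = 0.296), and no class passed. Anaerobically all 4 mutant libraries exceeded the same-numbered WT library in sRNA share. They stood at 27.2% and 27.9% against 22.1% for replicate 1 and at 30.2% and 30.4% against 26.5% for replicate 2. This difference was not tested by itself. Such shares are fractions of the counted features only, and their permutation p-values measure the spread between libraries. PCR copies were not marked with molecular identifiers, so the counts can include them.

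**Figure D2:**
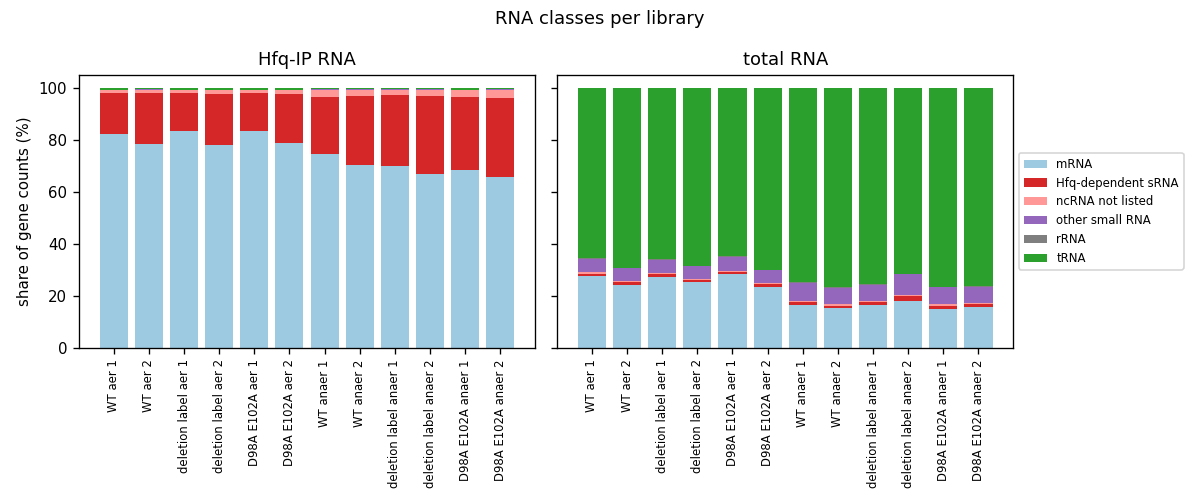
Share of the gene table's counts (percent, stacked bars, 1 bar per library) held by mRNAs, Hfq-dependent sRNAs, other listed small RNAs, unlisted ncRNAs, rRNAs and tRNAs in the 12 Hfq-IP libraries and the 12 total RNA libraries, ordered by growth condition (aer, aerobic; anaer, anaerobic) and strain. The sRNA part spans 14.5% to 30.4% in Hfq-IP RNA and the tRNA part 64.8% to 76.8% in total RNA.

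Which RNAs were enriched with Hfq was read from WT Hfq-IP RNA against WT total RNA. In aerobic cells the sRNAs led the enrichment. Among the largest fold changes were those of rprA (4.0 ± 0.45 log2, SE, n = 2 per group), an activator of rpoS translation, rydC (3.24 ± 0.54), chiX (3.18 ± 0.43), omrA (3.10 ± 0.22), oxyS (2.97 ± 0.29) and dsrA (2.94 ± 0.32), with sroC (3.13 ± 0.24, within gltI) and the small gene chiZ (3.17 ± 0.20, at chiP) among them. Of the 32 sRNAs, 30 rose and none fell, also 30 when adjusted over the list alone, with a median of 2.71 (camera adjusted p = 1.0e-16, and adjusted p = 0.026 with an estimated correlation). The 7 other stable small RNAs all fell, among them ssrS (-7.59), the 6S RNA that binds RNA polymerase, rnpB (-7.28), the RNA of RNase P, and csrB (-6.26 ± 0.21), which sequesters CsrA. All 14 antisense RNAs of type I toxins fell (sibA -6.36 ± 0.18), as did 84 of 86 tRNAs (tyrT -10.69 ± 0.39, alaU -10.36, leuU -10.30), and their camera adjusted p with an estimated correlation was 1.6e-06, 0.00044 and 2.9e-05 in that order. Of 20 rRNA genes 17 fell (rrfA -8.27), with an adjusted p = 1.2e-15 at the preset and adjusted p = 0.056 with an estimated correlation. The rRNA values, here and below, cover only the small part of the counts that rRNA held in both fractions. Gene hfq itself rose by 1.01 ± 0.14.

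Among mRNAs, 16 of 29 known sRNA targets rose and 4 fell, the same when adjusted over the list alone (median 0.93, adjusted p = 0.0080, and adjusted p = 0.55 with an estimated correlation). The chitoporin mRNA chiP rose by 2.57 ± 0.16, ptsG of the glucose transporter by 1.73 ± 0.13 and flhD, of the flagellar master regulator, by 2.52 ± 0.34, whereas lpp, the abundant outer membrane lipoprotein, fell by 2.84 ± 0.21. Ribosomal protein genes fell in 38 of 54 cases and rose in 4 (39 and 6 adjusted over the list alone, median -1.32, adjusted p = 7.7e-09, and adjusted p = 0.54 with an estimated correlation). Heat shock genes fell in 10 of 14 and rose in 2 (median -1.26, adjusted p = 0.0044, and adjusted p = 0.55 with an estimated correlation). Both of these medians turn positive, to 0.62 and 0.71, when libraries are scaled by their size alone. The remaining lists did not pass, with an adjusted p of 0.29 or more. Of them nitrate respiration had 4 genes up and 8 down of 18, fumarate and DMSO respiration 3 and 9 of 13, fermentation 1 and 4 of 11, the TCA cycle with aerobic respiration 3 and 8 of 25, and NADH dehydrogenase I 3 and 7 of 13, where nuoA at the head of the operon was 2.45 ± 0.24 higher. The other lists without a passing test were oxidative stress (3 up and 2 down of 10), the Fur iron regulon (5 and 7 of 27), the RpoS regulon (5 and 8 of 18, with rpoS at 1.71 ± 0.21), flagella and chemotaxis (6 and 1 of 25), sigma E envelope stress (5 and 6 of 15) and RNA binding and decay (2 and 6 of 11). For oxidative stress, the Fur regulon and sigma E the median was negative while the mean and the test pointed upward. With the lysate as a replicate block more genes were called in several of these lists. Fermentation then had 4 up and 4 down, the TCA cycle 6 and 15 and the Fur regulon 9 and 12.

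In all, 2288 of 4507 genes passed in edgeR, 1150 up and 1138 down, of which 1446 differed at least 2-fold. The balance between the directions rests on the TMM scaling. With library size alone the median gene moved up by 1.96 log2 and 3874 genes rose against 169 that fell; yhbS (-1.81 ± 0.23 with TMM), clpX and groL then changed sign, to 0.17, 0.34 and 0.15.

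The same comparison was made in the anaerobic WT libraries. Of the 32 sRNAs 29 rose and none fell (30 adjusted over the list alone, median 2.62, adjusted p = 5.3e-16, and adjusted p = 0.032 with an estimated correlation). Among the largest rises were those of flgO (3.22 ± 0.48), omrA (3.14 ± 0.22), gadY (3.07), sgrS (3.04), omrB (2.98), rprA (2.94), arcZ (2.87) and sdhX (2.83). All 7 other small RNAs (ssrS -7.94), all 14 type I antitoxin RNAs (sibA -6.16), 85 of 86 tRNAs (argU -10.61 ± 1.19) and 16 of 20 rRNA genes fell, and the 4 lists kept an adjusted p of at most 0.033 with an estimated correlation. Of 29 sRNA targets 16 rose and 2 fell (17 and 3 adjusted over the list alone, adjusted p = 0.0015, and adjusted p = 0.47 with an estimated correlation), with ompX at 1.80 and ptsG at 1.56. Ribosomal protein genes fell in 37 of 54 cases and rose in 7 (median -0.95, adjusted p = 3.4e-05, and adjusted p = 0.77 with an estimated correlation), and this median becomes 1.17 with library size alone. Gene hfq rose by 1.20 ± 0.14. In edgeR 2145 genes passed, 1123 up and 1022 down, 1320 of them at least 2-fold, and library size alone shifted the median gene by 2.13 and gave 4089 up and 144 down, with yhbS at 0.60 and clpX at 0.66 in place of -1.53 and -1.47. Every named gene of these aerobic and anaerobic comparisons, 8 in each direction, still passed when any 1 library was left out.

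**Figure D3:**
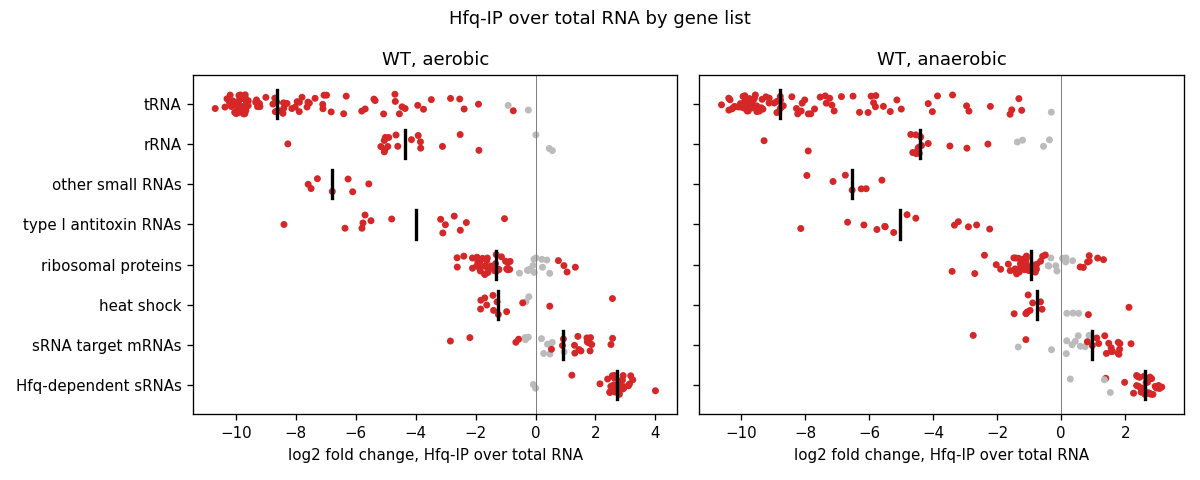
Log2 fold change of WT Hfq-IP over WT total RNA (x axis, TMM scaling) for the members of 8 gene lists, aerobic on the left and anaerobic on the right, 1 point per gene, red where the adjusted p was under 0.05, with a bar at each list's median. The sRNA medians are 2.71 and 2.62 and the tRNA medians -8.62 and -8.78; with library size alone the medians of ribosomal protein and heat shock genes become positive in both panels.

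The response to the growth condition was compared in WT total RNA. Anaerobic cells carried far more RNA of the acid resistance genes gadA (8.18 ± 0.54 log2), gadB (7.66) and gadC (7.52) and of hdeA (6.64) and hdeB (6.57), periplasmic acid chaperones, and of the hydrogenase 1 genes hyaA (7.01) and hyaB (6.77). They carried less of glpA (-7.60 ± 0.25) and glpC (-6.42), parts of the anaerobic glycerol-3-phosphate dehydrogenase, of the enterobactin genes fes (-6.79) and entC (-6.71) and of the ribosomal protein genes rplB (-6.53), rplV (-6.47) and rplW (-6.45). All 18 genes of the RpoS regulon rose (median 3.75, adjusted p = 1.1e-20, and adjusted p = 0.029 with an estimated correlation). All 54 ribosomal protein genes fell (median -3.76, adjusted p = 4.6e-72, and adjusted p = 0.066 with an estimated correlation). All 13 fumarate and DMSO respiration genes rose (dmsC 3.72, frdD 2.57) and all 13 NADH dehydrogenase I genes fell (nuoI -1.71), with adjusted p of 4.4e-07 and 2.2e-07, and adjusted p = 0.40 and 0.15 with an estimated correlation. Of 25 TCA cycle and aerobic respiration genes 21 fell and 2 rose (22 fell adjusted over the list alone; cyoD -5.85), and of 27 Fur regulon genes 21 fell and 6 rose (fhuA -3.81, sufC 3.40), each with adjusted p = 0.32 with an estimated correlation. Nitrate respiration divided into 7 genes that rose, such as napB (2.48) of the periplasmic nitrate reductase, and 8 that fell, such as nirB (-4.58) of the NADH-dependent nitrite reductase, and did not pass as a list (adjusted p = 0.66).

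Among 31 sRNAs in total RNA 15 rose and 8 fell, with narS at 2.48, rybB at 2.13 and sdhX at -2.35. Of the other lists, the anaerobic libraries had 5 of 7 other small RNAs up and none down (csrB 2.15), 6 of 14 antitoxin RNAs up and none down, 8 up and 14 down of 29 sRNA targets (ompT -4.23), 4 and 2 of 11 fermentation genes, and 4 and 3 of 10 oxidative stress genes, where the superoxide dismutase genes sodA (-5.51) and sodB (1.48) went opposite ways. There were 2 up and 3 down of 24 flagellar genes, 7 and 3 of 15 sigma E genes, 4 and 7 of 14 heat shock genes (ibpB -2.89, clpB 1.22), 1 and 5 of 11 RNA binding and decay genes (csrA 1.40), 7 of 20 rRNA genes down and none up, and 14 up and 8 down of 86 tRNAs (4 and 6 adjusted over the list alone). With library size alone the balance turned over for tRNAs (6 up and 10 down, median -0.07 in place of 0.13), fermentation (2 and 3) and oxidative stress (4 and 5), and antitoxin RNAs had 5 up and 2 down. In edgeR 2226 of 4184 genes passed, 1115 up and 1111 down. Library size alone moved the median gene by -0.20 and gave 853 up and 1260 down. In Hfq-IP RNA 2641 genes passed between the growth conditions, 1288 up and 1353 down, led by gadB (10.69), gadA (9.98) and the antisense RNA arrS (9.88) and, downward, by ybdZ (-7.65), glpA (-7.53) and entE (-7.48).

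The effect of the deletion label on Hfq-IP RNA was compared next. In aerobic Hfq-IP RNA heat shock mRNAs rose against WT, beside the yhbS locus and a cluster of initiator tRNA genes. The chaperone mRNA dnaK rose by 1.69 ± 0.19 log2 (SE, n = 2 per group, adjusted p = 0.0018), hslU, of the HslUV protease, by 1.25 and the chaperonin gene groS by 1.22. Of 14 heat shock genes 10 rose and none fell (12 adjusted over the list alone, median 1.19, adjusted p = 1.2e-28, and adjusted p = 0.084 with an estimated correlation; fry adjusted p = 0.0034). The feature tpke11, which overlaps the start of dnaJ, rose by 1.73 ± 0.23. The initiator tRNA genes metZ (2947387 to 2947463, plus strand) and metV (2947607 to 2947683) rose by 2.28 ± 0.21 and 2.04 ± 0.23, and metW between them by 1.53 ± 0.25 (adjusted p = 0.012, but up to 0.067 without 1 library). The metZ values were 96.6 and 95.6 CPM against 21.6 and 18.1 in WT. The fourth initiator gene, metY, lies elsewhere in the genome and differed by 0.02 ± 0.27. Over 84 tRNAs 3 rose and 1, trpT (-1.11, adjusted p = 0.13 without deletion-labelled replicate 2), fell.

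Ribosomal protein mRNAs fell in 8 of 54 cases under the same label (26 adjusted over the list alone, median -0.49, adjusted p = 5.1e-16, and adjusted p = 0.72 with an estimated correlation), with rplS and rplL both at -0.93 (adjusted p = 0.11 and 0.17 without deletion-labelled replicate 2). Of 32 sRNAs 0 passed in edgeR, none also when adjusted over the list alone, 7 had an unadjusted p under 0.05 and 3 a positive fold change (median -0.40, adjusted p = 0.00015, and adjusted p = 0.78 with an estimated correlation). In DESeq2 3 sRNAs passed downward, 2 with a replicate block, and 7 downward and 1 upward with a block within growth condition. Among them rybB and sroC passed in 3 alternatives each (adjusted p down to 0.0047 and 0.011). The tRNA list also passed upward (adjusted p = 0.0079, and adjusted p = 0.95 with an estimated correlation). Other genes that fell included cdaR (-1.16 ± 0.16), nupG (-1.14) and aldB (-1.08). In all 86 of 4497 genes passed in edgeR, 44 up and 42 down, and DESeq2 counted 299. Library size alone gave 88 up and 16 down after a shift of the median by 0.15. The 8 named genes that rose passed without any 1 library, but of the 8 that fell, 0 passed without deletion-labelled replicate 2. The count of genes was 20 without that library, 31 without deletion-labelled replicate 1 and 38 without WT replicate 2.

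In anaerobic Hfq-IP RNA of the deletion label, genes of the S10 ribosomal protein operon rose against WT, with rplD at 1.99 ± 0.25 log2 (adjusted p = 0.0054), rplW at 1.92, rplC at 1.88 ± 0.23, rplB at 1.79, rpsS at 1.78 and rpsJ at 1.73. The rplC values were 424 and 672 CPM against 145 and 153 in WT and 164 and 211 in the point mutant. Of 54 ribosomal protein genes 8 rose and none fell (28 adjusted over the list alone, median 0.45, adjusted p = 7.3e-22, and adjusted p = 0.69 with an estimated correlation). Of 14 heat shock genes 0 passed in edgeR (3 at an unadjusted p under 0.05), 1 in DESeq2, 1 with a replicate block and 3 with a block within growth condition. Gene dnaK at 0.56 ± 0.19 had an adjusted p of 0.18 in edgeR and 0.039 with the last block. Of 32 sRNAs 0 passed in edgeR, 1 when adjusted over the list alone, 10 had an unadjusted p under 0.05 and 25 were positive (median 0.33, adjusted p = 0.00060, and adjusted p = 0.69 with an estimated correlation). In DESeq2 3 rose and 1 fell, with a replicate block 3 rose, and with a block within growth condition 5 rose and 1 fell. Both mgrR and gcvB passed in all 3 (adjusted p down to 0.00020 and 0.0068). The RpoS regulon (median -0.23, adjusted p = 0.0079) and the tRNAs (median 0.32, adjusted p = 0.0047) also passed at the preset, with adjusted p = 0.69 and 0.76 with an estimated correlation. The tRNA gene metZ rose by 1.29 ± 0.21 (adjusted p = 0.019, and up to 0.24 without 1 library). Gene yibF (-1.52 ± 0.25) and agaA (-1.13) fell the most. In edgeR 29 genes passed, 20 up and 9 down, and 207 in DESeq2. Library size alone shifted the median by -0.20 and gave 20 up and 116 down. The count was 6 without deletion-labelled replicate 2, 3 without WT replicate 1 and 2 without WT replicate 2, and without WT replicate 1 only yhbP and yhbT passed of the 8 named genes that rose. Of the 8 named genes that fell, 0 passed without deletion-labelled replicate 2.

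The difference between the growth conditions was tested directly as an interaction. The response of rplC to the deletion label was 2.55 ± 0.32 log2 higher anaerobically than aerobically (adjusted p = 0.013), that of rplD 2.49 ± 0.34 and that of rpsJ 2.45 ± 0.32, while that of hslV was 1.77 ± 0.25 lower (log2 -1.77, adjusted p = 0.013). For acnA, an aconitase, the difference was -1.11 ± 0.20 (adjusted p = 0.049), and for metZ -0.98 (adjusted p = 0.13, but 0.049 in DESeq2, 0.033 with library size alone and 0.034 with a block within growth condition). Of 54 ribosomal protein genes 11 passed upward (44 adjusted over the list alone, median 1.01, adjusted p = 2.1e-42, and adjusted p = 0.22 with an estimated correlation; fry adjusted p = 0.015). Of 14 heat shock genes 1 passed downward (10 adjusted over the list alone, median -0.84, adjusted p = 8.3e-12, and adjusted p = 0.27 with an estimated correlation). Of 32 sRNAs 0 passed in edgeR, 5 when adjusted over the list alone, 7 in DESeq2, 3 with a replicate block and 9 with a block within growth condition, all upward. In edgeR 16 had an unadjusted p under 0.05 and 29 were positive (median 0.74, adjusted p = 4.8e-09, and adjusted p = 0.27 with an estimated correlation). In edgeR 17 genes passed, 14 up and 3 down, against 143 with a replicate block and 212 in DESeq2. That block holds only the replicate number, so the pairing of both growth conditions by culture was not modelled. Library size alone shifted the median by -0.34 and gave 15 up and 181 down. No gene passed without deletion-labelled replicate 2 of either growth condition or without either anaerobic WT library (0 in each case), 8 passed without the anaerobic and 10 without the aerobic deletion-labelled replicate 1, and 42 without aerobic WT replicate 2. The genes rplC, rplD and rpsJ kept their calls in 4 of 8 such fits, hslV in 2 and acnA in 0, at an adjusted p of at most 0.14, 0.13 and 0.18.

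Total RNA was compared to see which of these changes were already present before precipitation. In aerobic total RNA of the deletion label dnaK rose by 1.51 ± 0.20 log2, tpke11 by 1.53 and ydfZ by 1.54, while lldP, the lactate permease gene, fell by 1.17 and csiE by 1.15. Of 14 heat shock genes 8 rose and none fell (13 adjusted over the list alone, median 0.83, adjusted p = 3.9e-24, and adjusted p = 0.16 with an estimated correlation). Of 54 ribosomal protein genes 12 fell (39 adjusted over the list alone, median -0.58, adjusted p = 5.1e-24, and adjusted p = 0.37 with an estimated correlation). NADH dehydrogenase I, the RpoS regulon, fumarate and DMSO respiration and tRNAs passed downward at the preset with no gene called in edgeR (7, 5, 1 and 8 at an unadjusted p under 0.05, and 0, 1, 0 and 1 called in DESeq2; adjusted p = 0.00041, 0.00092, 0.026 and 0.0032), and with an estimated correlation at adjusted p = 0.37 or more; the tRNA median of -0.24 becomes 0.02 with library size alone. With a block within growth condition 8 NADH dehydrogenase I genes, 4 RpoS regulon genes and 4 fumarate and DMSO respiration genes were called downward. Among the tRNAs that block called 1, upward. In edgeR 54 of 4184 genes passed, 25 up and 29 down, and 145 in DESeq2. Library size alone moved the median by 0.26 and gave 39 up and 2 down. The count was 5 without deletion-labelled replicate 1, 11 without replicate 2, and 16 and 26 without WT replicates 1 and 2. Of the 3 named genes in each direction, none passed in all 4 of these fits (dnaK up to an adjusted p of 0.058).

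In anaerobic total RNA 8 genes rose and 1, yhbS, fell. The risers were yhbP and the ribosomal protein genes rplW (1.79), rplD (1.76), rplB (1.69), rplC (1.68), rplV (1.56), rpsC (1.24) and rplP (0.95), of which the last 4 were named after their values were seen. Over the 54 ribosomal protein genes 7 rose (29 adjusted over the list alone, median 0.43, adjusted p = 8.1e-30, and adjusted p = 0.72 with an estimated correlation). The edgeR count of 9 was 75 in DESeq2 and 0 without either WT library, and rplD then had an adjusted p of up to 0.16. Gene hfq was at -0.50 ± 0.14 and did not pass in edgeR (adjusted p = 0.20), but did with a block within growth condition (0.015).

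**Figure D4:**
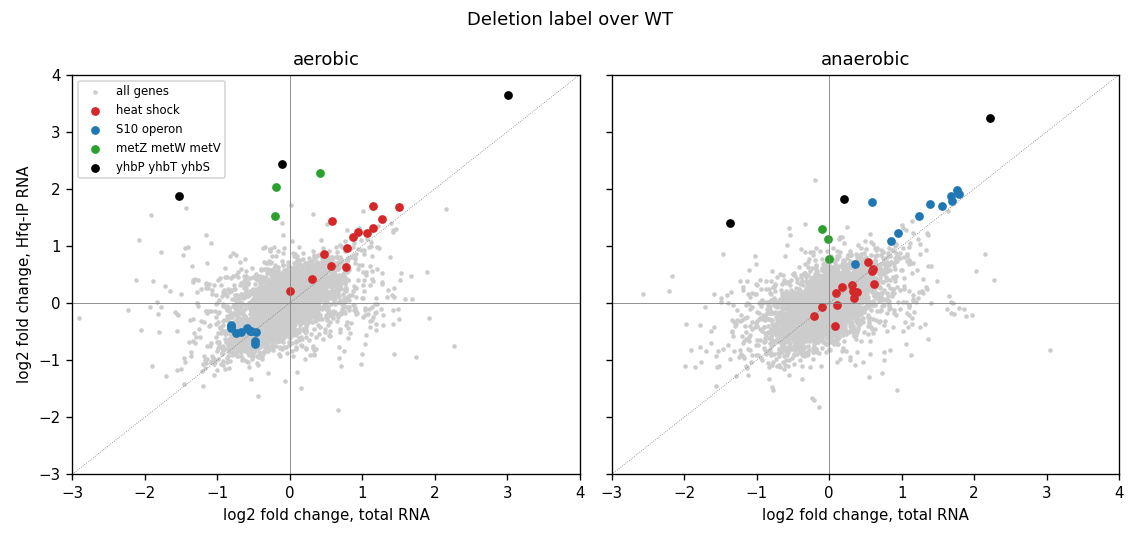
Log2 fold change of the deletion-labelled libraries over WT in total RNA (x axis) and in Hfq-IP RNA (y axis), 1 point per gene, aerobic on the left and anaerobic on the right, with heat shock genes, the S10 operon, metZ, metW and metV, and yhbP, yhbT and yhbS in colour and a dotted line where both axes are equal. Heat shock genes (aerobic medians 0.83 and 1.19) and S10 genes (anaerobic medians 1.39 and 1.73) lie near the line, while yhbS, yhbT and the 3 initiator tRNA genes lie above it.

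Change of Hfq-IP RNA beyond that of total RNA was tested as the difference between both fold changes. Under the deletion label 4 genes passed aerobically, all upward. They were yhbS (3.35 ± 0.32 log2), yhbT (2.50 ± 0.28), metV (2.19 ± 0.32) and metZ (1.81 ± 0.30), the last being named after its values were seen. Anaerobically 2 genes passed, yhbS (2.74 ± 0.32) and yhbT (1.59, adjusted p = 0.049). No sRNA passed in either growth condition in edgeR, in DESeq2 or with the lysate as a replicate block (1 in each at an unadjusted p under 0.05). The tRNAs passed as a list in both (adjusted p = 7.5e-11 and 1.3e-07, and adjusted p = 0.77 and 0.88 with an estimated correlation), and aerobically so did the RpoS regulon (median 0.41, adjusted p = 2.2e-06, and adjusted p = 0.37 with an estimated correlation). Heat shock genes had a median of 0.14 with none called in edgeR or DESeq2 (2 at an unadjusted p under 0.05; adjusted p = 0.022, and adjusted p = 0.95 with an estimated correlation), and type I antitoxin RNAs passed anaerobically (adjusted p = 0.0091, and adjusted p = 0.61 with an estimated correlation). With the lysate as a replicate block 9 genes passed aerobically, and 8 in DESeq2, against 5 in DESeq2 anaerobically. The gene metZ did not pass without deletion-labelled Hfq-IP replicate 2 (adjusted p = 0.053), deletion-labelled total replicate 2 (0.14) or WT Hfq-IP replicate 2 (0.12), and yhbT passed anaerobically in 1 of the 8 fits that left out a library (adjusted p up to 0.39). The aerobic count was 7 without WT Hfq-IP replicate 1 or WT total replicate 1, and the anaerobic count was 1 without 6 of the 8 libraries and 1 with library size alone, which shifted the median by -0.20.

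The point mutant D98A E102A, named for the 2 replaced residues of HqbA, had at most 2 genes past the threshold in edgeR against WT in any comparison. The level of the HqbA protein was not measured. In aerobic Hfq-IP RNA 2 genes passed in edgeR, metZ (1.97 ± 0.21 log2, SE, n = 2 per group, adjusted p = 0.0048) and metV (1.73 ± 0.23, adjusted p = 0.019). Their CPM were 76.2 and 78.7 for metZ and 237 and 331 for metV, against 21.6 and 18.1 and 96.6 and 74.2 in WT. The neighbour metW was at 1.24 ± 0.25 and did not pass in edgeR (adjusted p = 0.40), but did in DESeq2 (0.0031) and with a block within growth condition (0.029). At an unadjusted p under 0.05 there were 153 genes, and DESeq2 counted 5. Neither gene passed in every fit without 1 library, since metZ lost its call without WT replicate 1 (adjusted p = 0.052) or 2 (0.18) and metV without those libraries or point mutant replicate 2 (0.14, and 0.45 without WT replicate 2). In total RNA metZ was 0.18 and metV -0.10, neither passing. The tRNA list passed upward (adjusted p = 5.1e-13), the sRNA targets too, with 28 of 29 positive (median 0.15, adjusted p = 0.0025), and the ribosomal protein genes (median 0.10, adjusted p = 0.036), all 3 at adjusted p = 0.98 with an estimated correlation. Library size alone shifted the median gene by -0.06, and the medians of the sRNA targets and ribosomal protein genes were then 0.10 and 0.05.

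In anaerobic Hfq-IP RNA 0 genes passed for the point mutant in edgeR, with 149 at an unadjusted p under 0.05 and 1 in DESeq2. The smallest adjusted p in edgeR was 0.073, for chbC (1.13 ± 0.16), which passed in DESeq2, with either replicate block and with all 24 libraries in 1 fit (adjusted p at most 0.016). The sRNAs as a list were higher, with 29 of 32 positive, 8 at an unadjusted p under 0.05 and none called in edgeR, DESeq2 or with a block (median 0.35, adjusted p = 3.6e-12, and adjusted p = 0.30 with an estimated correlation). The other small RNAs (median 0.33, adjusted p = 0.0017, and adjusted p = 0.16 with an estimated correlation), the antitoxin RNAs (adjusted p = 0.0058) and the tRNAs (adjusted p = 0.0044) passed upward and NADH dehydrogenase I downward (adjusted p = 0.047), the last 3 at adjusted p = 0.79 or more with an estimated correlation. Library size alone moved the median gene by -0.11. The interaction of the point mutant with the growth condition had 0 genes in edgeR, 104 at an unadjusted p under 0.05 and 0 in DESeq2, and the sRNA list passed in it (median 0.49, adjusted p = 7.0e-11, and adjusted p = 0.37 with an estimated correlation). Gene metZ had an interaction of -1.16 that did not pass.

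Total RNA of the point mutant had 0 genes past the threshold in edgeR in either growth condition, with 95 aerobically and 112 anaerobically at an unadjusted p under 0.05 and 0 in DESeq2. Without WT total replicate 1 there were 2 aerobically. All 18 genes of the RpoS regulon had negative values aerobically (median -0.30, adjusted p = 2.0e-07, and adjusted p = 0.34 with an estimated correlation), and 27 of 31 sRNAs positive values anaerobically (median 0.20, adjusted p = 0.0017, and adjusted p = 0.95 with an estimated correlation). Enrichment beyond total RNA passed aerobically for metV (1.83) and metZ (1.79), both at adjusted p = 0.042, and DESeq2 also counted 2. Neither passed when any 1 of the 8 libraries was left out (adjusted p of 0.063 to 0.52), and the count was 0 with DESeq2 size factors, with the aerobic libraries alone, or with tRNA and rRNA features left out. Leaving out tRNA features removes metV and metZ by construction, so that count of 0 shows nothing about them. Anaerobically 0 genes passed, with 101 at an unadjusted p under 0.05 and 0 in DESeq2. Aerobically the tRNA list (adjusted p = 4.7e-08) and the RpoS regulon (adjusted p = 1.9e-05) passed, and anaerobically the ribosomal protein genes, downward (adjusted p = 0.025), with adjusted p = 1.00, 0.56 and 0.91 with an estimated correlation; with the lysate as a replicate block 4 and 3 lists passed in place of 2 and 1.

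Whether both mutants differed was tested directly between them. In aerobic Hfq-IP RNA the point mutant had less yhbP (-3.72 log2), yhbT (-2.54) and yhbS (-2.04 ± 0.23) than the deletion label, and more nanC (1.75), lldP (1.48) and ymfD (1.38). Of 14 heat shock genes 10 were lower (12 adjusted over the list alone, median -1.02, adjusted p = 5.3e-29, and adjusted p = 0.082 with an estimated correlation), and of 54 ribosomal protein genes 6 were higher (43 adjusted over the list alone, median 0.62, adjusted p = 1.8e-24, and adjusted p = 0.35 with an estimated correlation). The tRNA genes metZ and metV did not pass between the mutants in the full fit or without any 1 library. In edgeR 75 genes passed, 37 higher and 38 lower, and 262 in DESeq2; library size alone shifted the median by -0.21 and gave 15 higher and 109 lower. The count was 5 without point mutant replicate 1, 19 without its replicate 2, and 21 and 8 without deletion-labelled replicates 1 and 2, and of nanC, lldP and ymfD none passed in all 4 fits. Anaerobically 11 genes passed, 1 higher, uspB (0.87), and 10 lower, among them yhbP (-3.33), yhbT (-2.04), yhbS (-1.46) and rplD (-1.71), with 67 in DESeq2 and 2, yhbP and yhbT, without either point mutant library or deletion-labelled replicate 2. Ribosomal protein genes were lower in 7 of 54 cases (31 adjusted over the list alone, median -0.51, adjusted p = 1.2e-34, and adjusted p = 0.24 with an estimated correlation).

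Because both mutants were compared with the same WT libraries, the fold changes of metZ, heat shock and all other genes were set against simulated data with no effect. Across 4497 genes, which are not independent replicates, the fold changes of both mutants correlated with r = 0.359 aerobically, where 100 draws gave 0.431 to 0.548, and r = 0.495 anaerobically, where the draws gave 0.412 to 0.504. The covariance was 0.0507 against a simulated mean of 0.0539 aerobically and 0.0641 against 0.0476 (0.0413 to 0.0558) anaerobically. Among the 2329 genes with an average log2 CPM of at least 5, r was 0.325 aerobically (draws 0.451 to 0.553) and 0.551 anaerobically, above all draws (0.438 to 0.539), with a covariance of 0.0460 against 0.0247 to 0.0344. The draws treated all libraries as independent, whereas same-numbered libraries of a growth condition deviated together. That part cancels in the measured fold changes, so the draws are not an exact reference, and neither a shared effect nor its absence is read from them. Of the 44 genes up under the deletion label and the 2 up in the point mutant in aerobic Hfq-IP RNA, both metZ and metV were shared, against 0.0196 for independent lists. At an unadjusted p under 0.05, 26 genes were up in both against 4.96 and 42 down against 8.86 aerobically, and 37 against 6.31 and 35 against 5.95 anaerobically. With 2 WT libraries per group the controls could not be divided between the mutants. Any excess over these independent values may come in part or in whole from sharing them, so no shared effect is read from it.

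**Figure D5:**
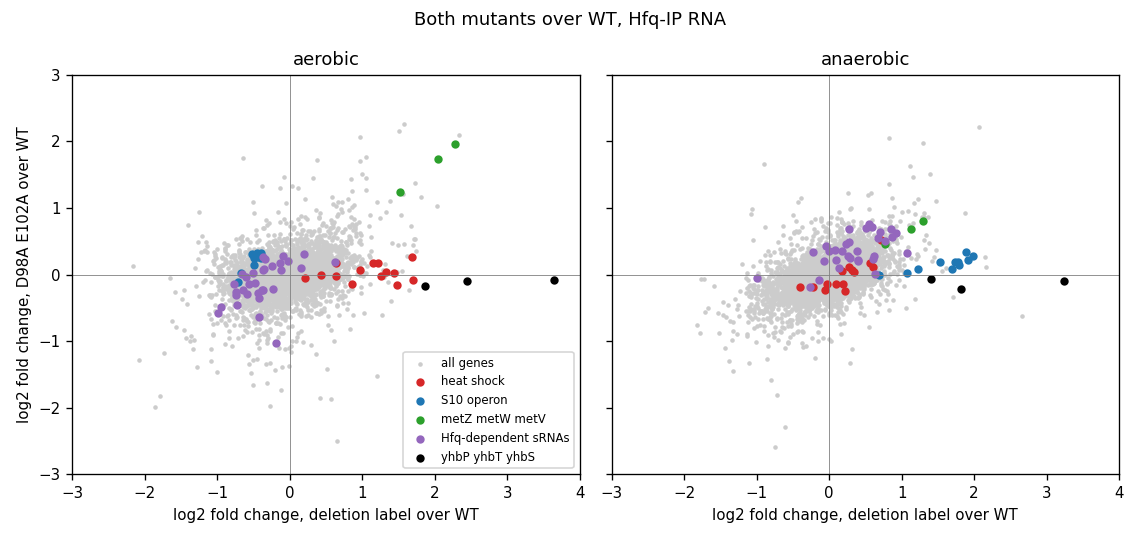
Log2 fold change over WT in Hfq-IP RNA for the deletion label (x axis) and the D98A E102A point mutant (y axis), 1 point per gene, aerobic on the left and anaerobic on the right, with named groups in colour. The genes metZ and metV are high on both axes in the aerobic panel (2.28 and 1.97 for metZ), whereas the heat shock genes (aerobic) and yhbP, yhbT and yhbS spread along the x axis near 0 on the y axis.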

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

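The tests in this part were chosen after the results were seen, apart from the pair that asked whether 1 library made the heat shock or S10 operon change and the test of the growth stage, whose predictions were written before their values were seen. What stood out was a difference between the growth conditions in how Hfq-IP RNA of the deletion label departed from WT. An interaction test found it for 17 genes, among them rplC (2.55), rplD (2.49) and rpsJ (2.45), whose log2 response was higher anaerobically, and hslV (-1.77) and acnA (-1.11), whose response was lower. Each of these named genes lost its call when certain single libraries were left out, as given with that test above.

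The first pattern is that heat shock mRNAs rose aerobically and S10 operon mRNAs anaerobically under the deletion label. For the heat shock genes a single divergent library is argued against. Even the lower of both libraries had a median log2 ratio to WT of 1.06, against a gap between the WT libraries of 0.328. For the S10 genes the lower median was 1.393, against a gap of 0.0746. For them the test cannot decide, because the operon was picked through genes named for lying above WT in both libraries. Stronger binding to Hfq at an unchanged RNA level is also argued against, because the medians in total RNA were 0.8315 ± 0.165 and 1.392 ± 0.169 (median SE of a single gene). Stronger binding on top of the higher RNA level is not excluded. The change beyond total RNA had a median of 0.1425 for the heat shock genes (-0.18 to 0.814) and 0.199 for the S10 genes (0.077 to 1.166). In edgeR 0 of them were called for it in either set. A culture collected at another stage of the shift to anaerobic growth cannot be told apart from a strain effect for the S10 genes, as the fold changes correlated across 4184 genes in total RNA with those of the growth response in the point mutant at r = -0.2212, between the bounds set for either reading. In total RNA edgeR called 8 of the 14 heat shock genes and 7 of the 11 S10 genes, so RNA levels differed between these libraries, and that the strain rather than the cultures made the difference remains a hypothesis.

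The second pattern is the higher metZ, metW and metV in aerobic Hfq-IP RNA of both mutants, which share the WT libraries. More tRNA of every kind was checked against the other tRNAs. They had a median log2 fold change of 0.216 with an SD of 0.419, against 1.89 for the 3 genes. This check cannot decide, because metZ and metV were named for their large rises in these same fold changes. Reads moved among the initiator tRNA genes are argued against. The sum of metZ, metW, metV and metY was at least 502.9 CPM in the mutant libraries and at most 268.5 in WT. Chance low values in the aerobic WT libraries alone were checked in the anaerobic libraries. There the median was 0.7875 ± 0.223 (SE of a single fold change), 1.12 under the deletion label and 0.69 in the point mutant. The check set these values against 0 and cannot decide, because the tRNAs as a list also rose there in both mutants at the preset. In the point mutant metZ lay at 0.54 to 1.05 there over 13 alternatives and did not pass. A biological difference of Hfq-bound initiator tRNA stays a hypothesis, and in each growth condition both mutants rest on the same 2 WT libraries, so their values are not independent.

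The third pattern is the excess of yhbP, yhbT and yhbS in the deletion-labelled Hfq-IP libraries. Single libraries swapped with another strain are argued against, as 8 of 8 deletion-labelled libraries lay outside the range of all others of their fraction and growth condition for yhbP and yhbS. An exchange of all libraries of the strain would give the same count. The test set for it could not tell, since yhbS was below all others in the 4 libraries of total RNA and above all others in the 4 of Hfq-IP RNA. Between the point mutant and WT labels, however, yhbS differed by only -0.59 to 0.14 log2 over all alternatives, fractions and growth conditions. An exchange would make either label the deletion, so their likeness at yhbS argues against it. A higher RNA level beside the altered locus may account for yhbP, which rose in total RNA by 2.219 log2 anaerobically (a call lost in 2 of 4 fits without 1 library) and more aerobically, but not for yhbT, whose total RNA differed by at most 0.204 ± 0.211. For yhbS, reads of yhbT that extend into it cannot be told apart from a remaining yhbS transcript, since its gain was 68.82% of that of yhbT and no table gives positions within genes.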

How the results depend on the processing

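Chosen after seeing the data were counting pairs instead of reads, a replicate block within each growth condition, and class shares of each mutant alone against WT or permuted among same-numbered libraries; the other alternatives were planned. The planned test of the tRNA table was not run, because its columns could not be assigned. Comparisons are named in a fixed order below, Hfq-IP RNA of the deletion label (aerobic, then anaerobic), of the point mutant, total RNA of the deletion label, and the point mutant against the deletion label in Hfq-IP RNA. Except where an alternative shows it by construction, the cause was not tested. Of the named genes' values under the alternatives, 3536 kept their direction and side of the threshold, 246 lost the call, 26 gained one, 54 moved and 5 reversed.

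With a minimum log2 change of 1, by construction, 1446 and 1320 genes remained between WT Hfq-IP and total RNA, 32 and 17 for the deletion label in Hfq-IP RNA, 20 in its aerobic total RNA and 36 between the mutants aerobically. With library size alone the counts were 4043 and 4233 for WT Hfq-IP against total RNA, 136 for the anaerobic deletion label, 124 between the mutants aerobically, 1 for anaerobic enrichment under the deletion label and 196 for its growth interaction, and yhbS (0.17 and 0.60), clpX (0.34 and 0.66) and groL (0.15) reversed between WT Hfq-IP and total RNA. With all 24 libraries in 1 fit the counts were 191 and 96, 1 for the anaerobic point mutant, 94 and 30 in total RNA, 1 for the point mutant in anaerobic total RNA, 190 and 26 between the mutants and 149 for the interaction. DESeq2 gave 299 and 207, 5 and 1, 145 and 75, 262 and 67 in the fixed order, 8 and 5 for enrichment under the deletion label and 212 for its interaction. Leaving out tRNA and rRNA features removes metZ and metV by construction and gave 0 for the point mutant aerobically, 2 for aerobic enrichment under the deletion label and 0 for that of the point mutant, which was also 0 with DESeq2 size factors and with the aerobic libraries alone. Counting pairs gave 17 for the deletion label in anaerobic total RNA.

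Strains share only a replicate number, and residuals of same-numbered libraries of 1 growth condition correlated at 0.18 to 0.41 in Hfq-IP and 0.11 to 0.32 in total RNA. With a replicate block the counts were 210 and 171, 1 for the anaerobic point mutant, 153 and 60, and 234 and 35; the interaction gave 143 and aerobic enrichment under the deletion label 9. A block within each growth condition gave 657 and 593, 4 and 1, 358 and 296, 574 and 242, and 534 for the interaction. Lists past the threshold with the block were 6 for the point mutant in anaerobic total RNA and 4 and 3 for its aerobic and anaerobic enrichment. The block moved no other count of genes or of lists past the threshold in the paired comparisons by over 1.5 times. Counts of called members within a list could move by more. In aerobic WT Hfq-IP against total RNA the TCA cycle had 6 up and 15 down in place of 3 and 8. With an estimated correlation 4 lists remained for aerobic WT Hfq-IP against total RNA, 1 each for WT growth in total and Hfq-IP RNA, and 0 in every comparison that involved a mutant, against 1 to 8 at the preset.

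Leaving out each library in turn gave 20 to 67 and 2 to 20 genes for the deletion label in Hfq-IP RNA, 0 to 2 for the aerobic point mutant, 5 to 26 and 0 to 12 for the deletion label in total RNA, 0 to 2 for the point mutant in aerobic total RNA, 5 to 21 and 2 to 11 between the mutants, 3 to 7 and 1 to 2 for enrichment under the deletion label, 0 to 1 for aerobic enrichment of the point mutant, 0 to 42 for the interaction of the deletion label and 0 to 1 for that of the point mutant. These fits assume that a lone library varies like the other groups. They also had no replicate block, so leaving out 1 library unbalances the replicate numbers. A deviation shared by same-numbered libraries then enters the fold change, and a lost call need not come from that library alone. For genes with an average log2 CPM of at least 5 the covariance between the mutants was 0.0261 aerobically, below all simulated values (0.0265 to 0.0349), and 0.0460 anaerobically, above all of them (0.0247 to 0.0344), with the simulation treating libraries as independent. At this number of libraries 62% of 2-fold changes in Hfq-IP RNA and 34% of 2-fold changes in enrichment were recovered in simulated data. A 2-fold change of a gene in the point mutant can therefore have been missed. The simulated data held 100 changed genes at each fold, all well counted, so these shares need not hold where few genes change. Smaller changes were not simulated.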

Other observations

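The sRNAs of WT Hfq-IP RNA changed between growth conditions in both directions. Their share of the counts averaged 17.6% aerobically and 24.3% anaerobically, a difference that was not tested. In anaerobic Hfq-IP RNA sdsR, an RpoS-dependent sRNA, was higher by 5.68 ± 0.34 log2 (edgeR adjusted p = 6.5e-08, n = 2 per group), micF, which represses ompF, by 3.63 ± 0.30, gadY, a regulator of acid resistance, by 2.48 ± 0.30 and omrA by 1.63 ± 0.19. Going down were ryhB, the sRNA of iron limitation (-5.08 ± 0.32), oxyS, the sRNA of peroxide stress (-2.36 ± 0.33), and sdhX (-2.21 ± 0.20). Of 32 sRNAs 12 rose and 10 fell, the same when adjusted over the list alone, and the list did not pass (median 0.16, adjusted p = 0.70). Gene hfq rose by 0.48 in Hfq-IP RNA (adjusted p = 0.014), but the call was lost without aerobic replicate 1 (adjusted p = 0.072) and without anaerobic replicate 1 (adjusted p = 0.13), and in total RNA its value of 0.34 did not pass (adjusted p = 0.068, but 0.0060 with a replicate block within growth condition).

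In WT Hfq-IP RNA the mRNAs of several lists followed the growth condition as well, in the same direction as in total RNA. Whether they changed beyond total RNA between growth conditions was not tested. All 18 genes of the RpoS regulon rose in Hfq-IP RNA (median 4.29, adjusted p = 1.0e-27, and adjusted p = 0.039 with an estimated correlation), with dps at 5.18 ± 0.19. Of 54 ribosomal protein genes 52 fell (median -3.14, adjusted p = 1.7e-46, and adjusted p = 0.10 with an estimated correlation). All 13 fumarate and DMSO respiration genes rose (median 2.68, adjusted p = 2.0e-06) and all 13 NADH dehydrogenase I genes fell (median -1.46, adjusted p = 0.00013), while 21 of 27 Fur regulon genes fell and 6 rose, and these 3 had an adjusted p = 0.37 or more with an estimated correlation.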
